A study of Mus musculus with 120 samples.

How the data were processed

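Bacterial 16S rRNA gene amplicons were sequenced from colonic and cecal contents of C57BL/6N mice. The mice were 10 weeks old, were acclimatised for 7 days and then held for 42 days under 1 of 5 light cycles, with or without antibiotics in the drinking water. The design names 240 mice, 24 per combination of diet and light cycle, and 120 samples from them were analysed here. The deposited table holds counts of reads per amplicon sequence variant and sample, with no normalisation, and a taxonomy table made by the authors gives each variant's names from domain to species. Per the labels, DNA was extracted with a stool kit and sequenced from PacBio SMRTbell libraries. The denoiser, the primers, the read filters and the taxonomy database are not given in the sources used here.

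The table holds 13844 sequence variants in 120 samples. Total counts per sample ranged from 39157 to 73076, with a mean of 63733.8. Counts were summed by genus, giving 583 genus names, and counts without a genus were summed under their lowest named rank and called unclassified members of it. The 629 variants with no taxon at all made up at most 0.441% of the counts of any sample and were left out of the genus tests but kept in the total. Amplicon reads carry no molecular identifiers, so depth speaks for counting error only. No sample was a copy of another among the 301 pairs compared.

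Genera were tested with edgeR 4.0.16 (quasi-likelihood, robust) under R 4.3.3, with the total count as library size and no composition factor. Genera needed at least 3 counts in at least 5 samples of a fit. P values were adjusted with the Benjamini-Hochberg method over all genera tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Diets were compared within each site with light cycle as a factor, sites within each diet likewise, and light cycles within each site and diet, first for any difference and then each against LD12/12. An interaction test asked whether light cycle effects differed between diets. The sample details used here give no cage, so all tests treated the samples of a group as independent. Differences between cages therefore could not be told apart from those between light cycles or diets. The tests were also run on simulated counts with the mean of each genus, its spread and the library sizes taken from the data, where 83.7% of 8-fold changes were recovered in the comparison of diets in the colon, 45.3% for LD24/0 against LD12/12 in the colon on chow, and 7.81% for the same contrast in the cecum on chow. Up to 200 genera were changed per simulation, where the real fits tested 258, 222 and 185, so most or all were changed. Adjustment over genera is more lenient when many change, so recovery may be lower where few do.

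The Shannon index (natural logarithm) and the expected number of variants at a common depth of 39157 counts were compared by two-sided permutation tests with 100000 resamples, labels being permuted within light cycles for diets and sites. The smallest p these can give is 1e-05. Pairs of light cycles were compared by exact permutation tests, adjusted over the 4 contrasts of a site and diet. Community composition was compared on Bray-Curtis distances between relative abundances of variants with adonis2 of vegan 2.7.1 and 99999 permutations. Own code in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the permutations, and figures were drawn with matplotlib 3.10.9.

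The tests, the alternatives, the lists of taxa and the rule for naming genera were fixed before the data were examined. The rule took genera past the threshold with a mean of at least 0.1% in a compared group. It took the 12 with the largest change in each direction between diets, the 6 in each direction with the smallest p between sites, the 10 with the smallest p for any light cycle, the 4 in each direction with the smallest p for each light cycle, and the 6 with the smallest p for the interaction, and it added any member of the lists. The lists were short-chain fatty acid producers among the Clostridia, Bacteroidales of the mouse gut, lactic acid bacteria and bifidobacteria, Enterobacterales, enterococci and staphylococci, mucin degraders and mucus-layer genera, sulfate reducers, Erysipelotrichales, and reagent and environmental genera with plastids.

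After the data were examined, 165 variants of 20 genera were found at even, low levels in groups of libraries that crossed the study's groups. These 20 genera are called background genera below. Their summed share of counts is that of the 165 variants only, each below 2% in every sample, while tests and calls are of whole genera. A tree of the shares of these variants was split until no branch held more than 8 libraries, which gave 11 sets of 7 to 8 libraries covering 86 samples, and 34 samples held too little of them to be placed. The sets are defined from the data and are not named in the labels. Alternatives fixed beforehand were TMMwsp composition factors, DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log-ratios with 0.5 added to every count, no filter on low counts, the replicate number as a block, leaving out each sample in turn, and other depths, distances and taxonomic levels for diversity. Alternatives added after the data were examined were the set as a block, genera reaching 2% in at least 1 sample of a fit, and the diets within 1 set. Whether replicate numbers pair colonic with cecal samples of 1 mouse is not stated, and the data showed no clear pairing. By number, 12 of 30 chow pairs and 9 of 29 antibiotics pairs correlated above 0.1. The cecal sample of the same number was the best match in 7 and 1 of them. This check cannot exclude pairing.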

Results

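The series profiled the bacteria of the colon and the cecum of mice under 5 light cycles on a chow diet or on the same diet with broad-spectrum antibiotics in the water. The light cycles gave 0, 8, 12, 16 or 24 h of light per day (LD0/24, LD8/16, LD12/12, LD16/8 and LD24/0). There were 20 groups of 6 samples, except 5 in the antibiotics group of LD8/16 in the colon and 7 in the chow group of LD8/16 in the cecum. Total counts ranged from 39157 to 69739 in the colon on chow, from 53336 to 68599 in the colon with antibiotics, from 56537 to 73076 in the cecum on chow and from 59341 to 71113 in the cecum with antibiotics. The background genera took a mean of 3.21% of counts in the colon on chow, 3.77% in the colon with antibiotics, 0.269% in the cecum on chow and 3.18% in the cecum with antibiotics.

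The comparison of diets asked how antibiotics changed the community at each site. In the colon, antibiotics replaced a community led by Ligilactobacillus and unclassified Muribaculaceae with one led by Parabacteroides and Klebsiella. Klebsiella, a facultative anaerobe of the Enterobacterales, made up 31.3% ± 16.9 (SD, n = 29) of counts with antibiotics and 0.567% ± 0.163 (SD, n = 30) on chow. It rose by a log2 fold change of 5.72 ± 0.27 (SE, edgeR adjusted p = 3.37e-28) and stood above the chow mean in 29 of 29 samples. Pantoea rose by 5.17 ± 0.28, Parabacteroides by 4.66 ± 0.29 and Enterobacter by 3.04 ± 0.30, each above the chow mean in 29 of 29 samples. Enterococcus rose by 4.35 ± 0.48 and stood above the chow mean in 21 of 29 samples. Bacteroides rose by 3.87 ± 0.57 in the model, although only 12 of 29 samples stood above the chow mean, at 12.4% ± 22.6 (SD, n = 29). On chow, Klebsiella, Parabacteroides, Bacteroides, Enterococcus and Pantoea together took 1.61% to 3.70% in the 29 colon libraries placed in sets. The 1 library outside the sets held 0.189%. Carry-over between libraries, left open below, would raise these chow shares and make the rises look smaller. Unclassified Muribaculaceae fell by 5.84 on the log2 scale, from 19.4% to 0.331% of counts, and Ligilactobacillus fell by 5.56, from 30.2% to 0.63%. Desulfovibrio, a sulfate reducer, fell by 5.74, and the Lachnospiraceae NK4A136 group fell by 5.26. Each of these 4 was below the chow mean in 29 of 29 samples.

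By list, 19 of 25 tested short-chain fatty acid producers fell in the colon, 1 rose and 5 did not pass, with 19 falling and 1 rising when adjusted over the list alone. All 4 mucin degraders and mucus-layer genera fell, among them Akkermansia by 3.90 and Helicobacter by 4.58 on the log2 scale, and all 3 sulfate reducers fell, with the same counts adjusted over the list alone. Of 12 Bacteroidales, 8 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone, while their summed share rose from 23.4% to 44.2% of counts (permutation p = 1e-05). Of 7 Enterobacterales, 4 rose and 3 did not pass, and 4 rose when adjusted over the list alone. Of 3 enterococci and staphylococci, 1 rose, and of 4 Erysipelotrichales 3 fell, with the same counts adjusted over the list alone. Among 12 lactic acid bacteria and bifidobacteria, 5 rose and 4 fell, and 6 rose and 4 fell when adjusted over the list alone. The members that rose include Lactiplantibacillus and Weissella, which are background genera. Lentilactobacillus, a background genus outside the list, rose as well. The summed share of this list went the other way, from 35.9% on chow to 3.31% with antibiotics (permutation p = 1e-05). Of 12 reagent and environmental genera and plastids, 3 rose, with the same count adjusted over the list alone. Neisseria, Haemophilus, Leptotrichia and Veillonella, also background genera, were among those that fell, and Neisseria and Leptotrichia were counted in 0 of 29 samples with antibiotics. In all, 141 of 258 genera passed, 23 rising and 118 falling, and 14 of the 141 were background genera. Only 1 set of libraries held colon samples of both diets, so diet is largely confounded with set. The median log2 fold change was -3.48 and moved by 1.04 with TMMwsp factors, which gave 50 rising and 106 falling, while limma on centred log-ratios gave 107 rising and 93 falling.

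**Figure D1:**
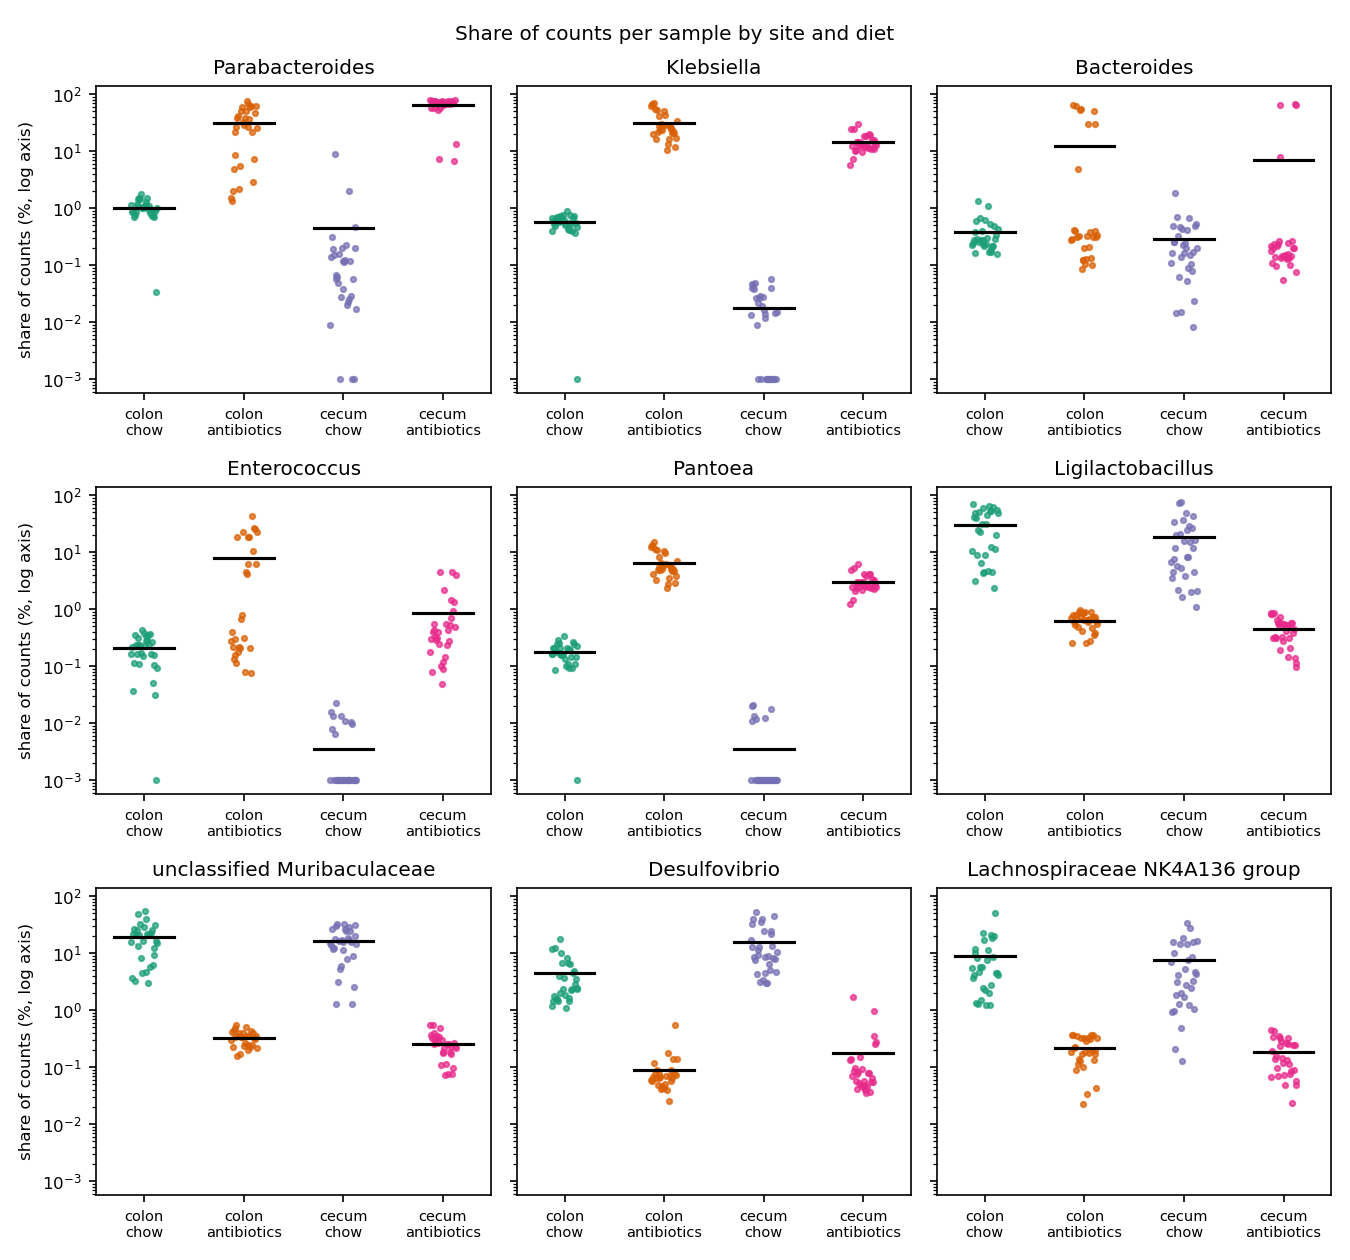
Share of counts per sample (percent, log axis, shares under 0.001% drawn at 0.001%) of 9 genera in the colon and cecum on each diet; points are samples and black lines are means. Klebsiella averages 31.3% in the colon with antibiotics and 0.567% on chow, while Ligilactobacillus averages 0.63% and 30.2%.

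In the cecum the same leading genera changed. Parabacteroides made up 64.4% ± 19.9 (SD, n = 30) of counts with antibiotics and 0.454% ± 1.64 (SD, n = 31) on chow, a rise of 8.13 ± 0.62 on the log2 scale (SE, edgeR adjusted p = 6.82e-19). Klebsiella rose by 9.90 ± 0.60 to 14.5% and Pantoea by 10.61 ± 0.69 to 3.05%, and each, like Parabacteroides, stood above the chow mean in 30 of 30 samples. Bacteroides rose by 1.84 ± 0.50, with 4 of 30 samples above the chow mean. Desulfovibrio fell by 6.98, from 15.9% to 0.177%, unclassified Muribaculaceae fell by 6.09, Odoribacter fell by 7.83 and Enterorhabdus fell by 9.44, each below the chow mean in 30 of 30 samples. Of 26 short-chain fatty acid producers, 18 fell, 2 rose and 6 did not pass. All 4 mucin degraders and mucus-layer genera, all 3 sulfate reducers and all 5 Erysipelotrichales tested fell, and 5 of 7 Enterobacterales rose. Of 12 Bacteroidales 7 fell and 4 rose, of 8 lactic acid bacteria and bifidobacteria 2 fell and 4 rose, and of 4 enterococci and staphylococci 1 rose and 1 fell. For 2 lists the summed share went against these counts, as Bacteroidales took 24.3% on chow and 71.9% with antibiotics, and lactic acid bacteria and bifidobacteria 22.8% and 2.17% (permutation p = 1e-05 for each). Of 13 reagent and environmental genera and plastids, 9 rose and 1 fell. Every list of this site had the same counts adjusted over the list alone. The background genera Limosilactobacillus, Leptotrichia, Veillonella, Haemophilus, Neisseria and Actinomyces also rose, where background genera took 3.18% of counts against 0.269% on chow. In all, 191 of 255 genera passed, 72 rising and 119 falling, and the median log2 fold change of -2.86 moved by 0.43 with TMMwsp factors. Of the 30 antibiotics libraries 28 lie in sets and none of the chow libraries does, so diet and set cannot be told apart here.

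Antibiotics lowered diversity at both sites. The Shannon index was 2.22 ± 0.40 (SD, n = 29) with antibiotics and 4.08 ± 0.978 (SD, n = 30) on chow in the colon, a difference of -1.87, and 2.45 ± 0.299 (SD, n = 30) and 3.94 ± 1.00 (SD, n = 31) in the cecum, a difference of -1.51. Both permutation p values were 1e-05, the smallest possible. Observed variants fell by 505 in the colon and fell by 413 in the cecum (permutation p = 1e-05 for each). The antibiotics effect did not differ detectably between sites (permutation p = 0.196 for the Shannon index and 0.118 for observed variants). Diet accounted for 47.3% of the variation in Bray-Curtis distance in the colon and 51.8% in the cecum (permutation p = 1e-05, the smallest possible).

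**Figure D2:**
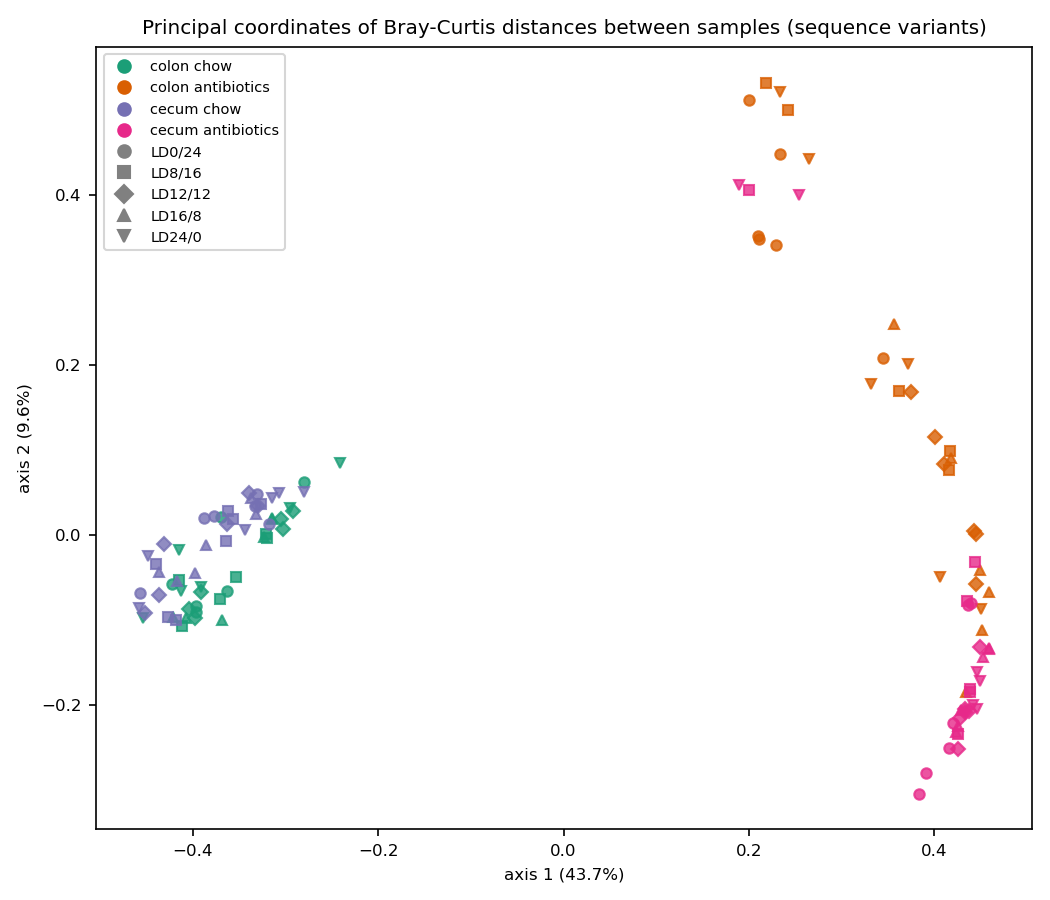
Principal coordinates of Bray-Curtis distances between the 120 samples; colours give site and diet, and symbols give light cycle. Samples with antibiotics lie apart from chow samples, and on chow the symbols of the light cycles overlap on these 2 axes. In the colon with antibiotics, LD0/24 lies at 0.208 or more on axis 2 and LD12/12 at 0.168 or less.

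The comparison of sites asked how the cecum differs from the colon within each diet. On chow, Desulfovibrio was higher in the cecum, at 15.9% ± 14.0 (SD, n = 31) against 4.44% ± 4.10 (SD, n = 30), by 1.85 ± 0.35 on the log2 scale (SE, edgeR adjusted p = 7.63e-06) and above the colon mean in 25 of 31 samples. Enterorhabdus was higher by 1.78 ± 0.34, Odoribacter by 1.87 ± 0.38 and Rikenella by 2.07 ± 0.47, each above the colon mean in 25 of 31 samples. Pediococcus, Haemophilus, Leptotrichia, Limosilactobacillus, Neisseria and Lactiplantibacillus were lower in the cecum, and all 6 are background genera, which took 0.269% of counts there and 3.21% in the colon. Of 272 genera, 85 passed, 29 higher and 56 lower in the cecum, and 17 of the 85 were background genera. The median log2 difference of -0.15 moved by 0.73 with TMMwsp factors, which gave 66 higher and 50 lower, while limma on centred log-ratios gave 80 higher and 54 lower. With antibiotics, Parabacteroides was higher in the cecum by 1.34 ± 0.28 and above the colon mean in 27 of 30 samples, while Klebsiella fell by 1.04, Pantoea fell by 1.05 and Enterococcus fell by 2.51 on the log2 scale from colon to cecum, each below the colon mean in 30 of 30 samples. Of 215 genera, 68 passed, 45 higher and 23 lower in the cecum, and 16 were background genera. Here the median of -0.11 moved by -0.51 with TMMwsp factors, which gave 45 higher and 43 lower, while limma on centred log-ratios gave 51 higher and 71 lower, so the balance of directions depends on the scaling. No set of libraries held samples of both sites on the same diet, so site and set cannot be told apart. Site accounted for 8.5% of the variation in Bray-Curtis distance on chow and 26.2% with antibiotics (permutation p = 1e-05, the smallest possible). The Shannon index was higher by 0.233 in the cecum than in the colon with antibiotics (permutation p = 0.0104), but on genera the difference was -0.276.

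The light cycles were compared to ask whether day length changes the community. On chow, few abundant gut genera passed. In the colon, 49 of 222 genera passed the test for any light cycle, and of the 10 named by the rule 7 were background genera, among them Lentilactobacillus, Limosilactobacillus and Fusobacterium. None of 12 Bacteroidales and none of 3 sulfate reducers passed, over all genera or adjusted over the list alone. Of 29 genera reaching 2% in a sample, 1 passed, and with the set as a block 0 of 221 passed by edgeR, 23 having an unadjusted p under 0.05. No chain of shared sets links LD0/24, LD16/8 or LD24/0 to LD12/12 here, so the block does not test these light cycles against it. Against LD12/12, LD24/0 changed 40 genera, 9 rising and 31 falling, of which 14 were background genera, and LD16/8 changed 8, all falling. LD0/24 changed 4 by edgeR, and 10 by TMMwsp factors and by DESeq2. LD8/16 changed 0 by edgeR, with 19 at an unadjusted p under 0.05, and 1 by DESeq2. Enterobacterales took 0.811% ± 0.392 (SD, n = 6) of counts in LD24/0 and 1.33% ± 0.292 (SD, n = 6) in LD12/12 (exact permutation p = 0.00433, adjusted p = 0.0173). The LD24/0 mean includes replicate 5 at 0.0153%, the others averaging 0.97%. With the set as a block the light cycles did not pass (permutation p = 0.467), but this test cannot compare LD24/0 with LD12/12. In the cecum on chow, Dubosiella passed for any light cycle (edgeR adjusted p = 0.00579), among 29 of 185 genera, but its highest mean, in LD16/8, rests on 1 library at 21.7%, with 0.0251% in the others. It kept its call with any 1 library left out, while the other 5 of the 6 genera named by the rule lost theirs. Against LD12/12, edgeR called 0 genera in LD0/24, LD8/16 and LD16/8, with 26, 22 and 34 at an unadjusted p under 0.05, while DESeq2 called 5, 5 and 1. LD24/0 changed 7 by edgeR and 0 with TMMwsp factors. Light cycle accounted for 14.4% of the variation in Bray-Curtis distance in the colon (permutation p = 0.351) and 12% in the cecum on chow (permutation p = 0.714). On other distances the call changed: it accounted for 17.5% with Jaccard and 28.4% with Aitchison distance in the colon (permutation p = 1e-05 for each), and for 18.8% with Aitchison distance in the cecum (permutation p = 0.00056). These 2 distances were not run with the set as a block, so in the colon they do not separate light cycle from set. With the block, Bray-Curtis distance gave 8.83% in the colon (permutation p = 0.712).

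With antibiotics the abundant genera of the colon differed between light cycles. Klebsiella averaged 48.7% of counts in LD0/24 and 19.7% in LD16/8 (edgeR adjusted p = 0.018 for any light cycle), Parabacteroides averaged 6.66% in LD0/24 and 54.8% in LD16/8 (adjusted p = 0.0258), and Enterococcus averaged 22.5% in LD24/0 and 0.246% in LD0/24 (adjusted p = 0.0268). These 3 and Pantoea, Anaeroplasma and unclassified Clostridia vadinBB60 group were the 6 of 46 genera called with the set of libraries as a block as well, at adjusted p values of 0.0294, 0.0297, 0.0294, 0.0341, 0.00234 and 0.00591 for Klebsiella, Parabacteroides, Enterococcus, Pantoea, Anaeroplasma and the Clostridia group. Anaeroplasma took 7.24% in 1 library of LD0/24 and 0.191% in the others of that group. The summed shares of Enterobacterales and of enterococci and staphylococci passed for any light cycle without the block (adjusted p = 0.0369 and 0.0143) and not with it (adjusted p = 0.0521 and 0.0999). The same held for lactic acid bacteria and bifidobacteria (adjusted permutation p = 0.00144 without the block and 0.315 with it). Against LD12/12, Parabacteroides fell by 2.70 on the log2 scale in LD0/24 and Bacteroides rose by 7.40 ± 2.24 (SE), to 21.6% ± 33 (SD, n = 6) from 0.128% (edgeR adjusted p = 0.0284 and 0.0389). LD0/24 changed 19 genera, 16 rising and 3 falling, and with TMMwsp factors 4, 2 rising and 2 falling. LD8/16 changed 12, 4 rising and 8 falling, and from 6 to 12 with 1 sample left out. Among the 12 were Robinsoniella, which rose by 8.21 ± 1.79, and Bifidobacterium, a background genus here, which fell by 9.04 from an LD12/12 group with 3.04% in 1 library and a mean of 0.51% in the others. LD16/8 changed 1, and LD24/0 changed 25, 17 rising and 8 falling, with Pediococcus and Lentilactobacillus, both background genera, among those that fell. With the set as a block, no call against LD12/12 was kept in LD0/24, LD16/8 or LD24/0, and no chain of shared sets links LD8/16 to LD12/12. LD0/24 and LD24/0 share no set with LD12/12 and are linked to it only through LD16/8, of which replicates 5 and 6 do. The lost calls of LD0/24 and LD24/0 thus cannot tell sets from light cycle. The Shannon index was 1.70 ± 0.243 (SD, n = 6) in LD0/24 and 2.36 ± 0.176 (SD, n = 6) in LD12/12 (exact permutation p = 0.00216, adjusted p = 0.00866), and the index also differed between light cycles with the set as a block (permutation p = 0.00208), but not detectably on genera in place of variants (permutation p = 0.102). Light cycle accounted for 39.2% of the variation in Bray-Curtis distance (permutation p = 0.00049), and 29.6% after the set of libraries (permutation p = 0.00022).

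**Figure D3:**
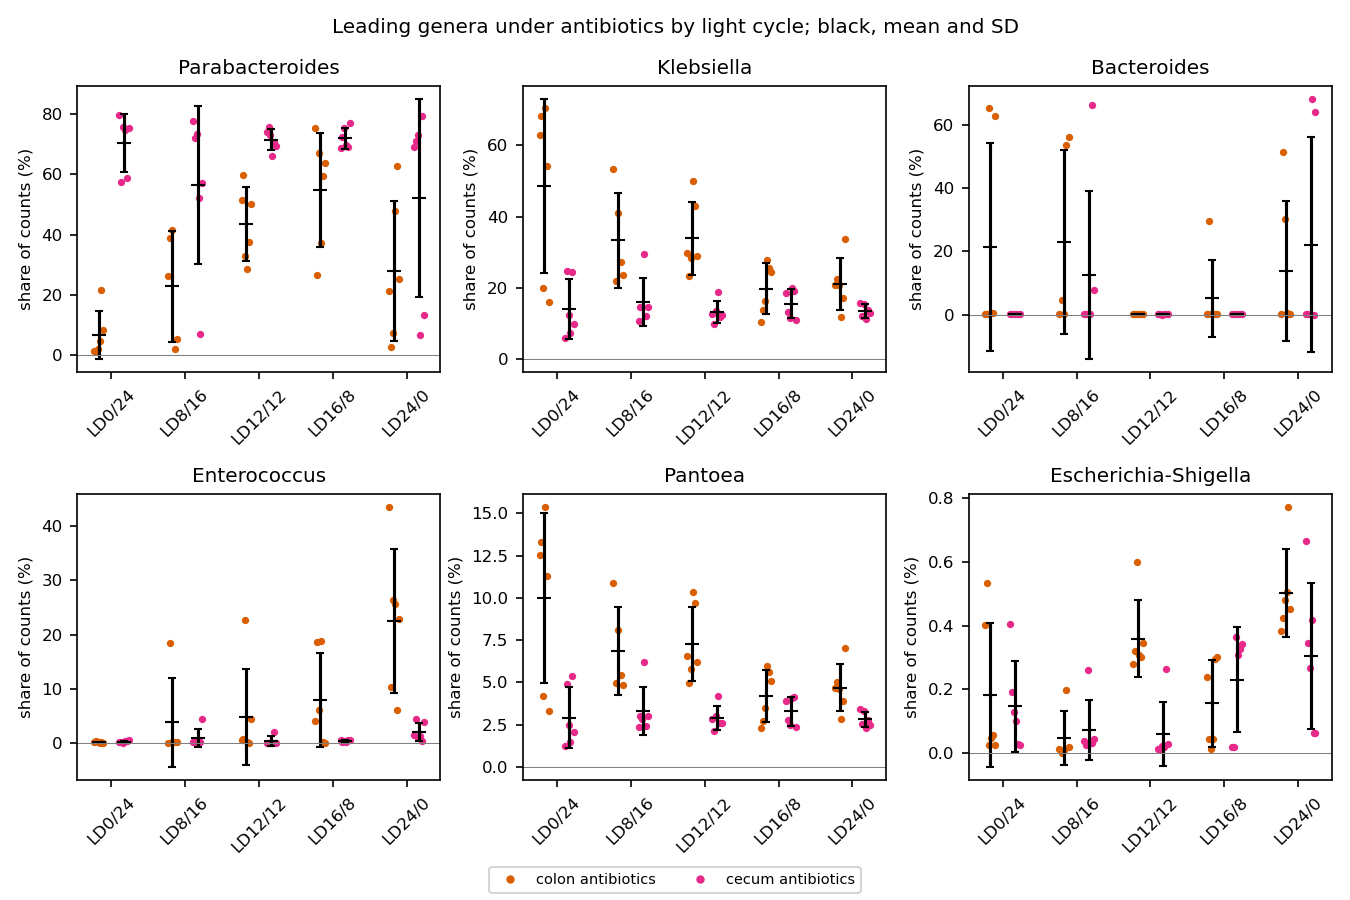
Share of counts (percent) of 6 genera with antibiotics by light cycle; points are samples of the colon or cecum, and black marks are means with SD. Klebsiella in the colon averages 48.7% in LD0/24 and 19.7% in LD16/8.

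In the cecum with antibiotics, Bacteroides was highest in LD24/0 at 22.2%, with 68.2% in replicate 4 and a mean of 13% in the others, and lowest in LD12/12 at 0.128% (edgeR adjusted p = 0.000833 for any light cycle). The mean of the others need not be even. On axis 2 of the principal coordinates, replicates 4 and 6 of LD24/0 lay at 0.412 and 0.400, and its other libraries at -0.162 or lower. Against LD12/12, Bacteroides rose by 7.44 ± 1.79 in LD24/0. In LD8/16 it rose by 6.61 ± 1.73, where 1 library held 66.2% and the others averaged 1.74%. Desulfovibrio rose by 2.72 ± 0.74 in LD0/24, where 1 library held 1.68% and the others averaged 0.106%, and by 2.56 ± 0.73 in LD24/0, with 0.986% in 1 library and 0.198% in the others, against 0.0557% in LD12/12. Robinsoniella rose by 6.88 ± 1.78 and the Ruminococcus gnavus group fell by 5.25 in LD8/16. In all, 28 of 158 genera passed for any light cycle, and with the set as a block 0 of 156 passed by edgeR, 13 having an unadjusted p under 0.05. LD0/24 changed 2 genera, LD8/16 14 (11 rising, 3 falling) and LD24/0 12 (8 rising, 4 falling). With the set as a block, 0 of the 12 LD24/0 calls were kept. LD24/0 shares no set with LD12/12 and is linked to it only through LD16/8, of which replicates 1 and 2 do. No chain of shared sets links LD0/24 or LD8/16 to LD12/12, so light cycle and set cannot be told apart there. LD16/8 changed 0 by edgeR and by DESeq2, with 22 and 14 at an unadjusted p under 0.05. Lactic acid bacteria and bifidobacteria took 1.23% ± 0.735 (SD, n = 6) in LD24/0 and 2.27% ± 0.219 (SD, n = 6) in LD12/12 (exact permutation p = 0.00649, adjusted p = 0.013), and with the set as a block the light cycles did not pass (permutation p = 0.909). LD24/0 replicates 5 and 6, with 0.147% and 0.131% of background genera, to which several members of this list belong, lie in no set and were left out of that test. Light cycle accounted for 27.5% of the variation in Bray-Curtis distance (permutation p = 0.0247), and the call ended with the set as a block (permutation p = 0.282).

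**Figure D4:**
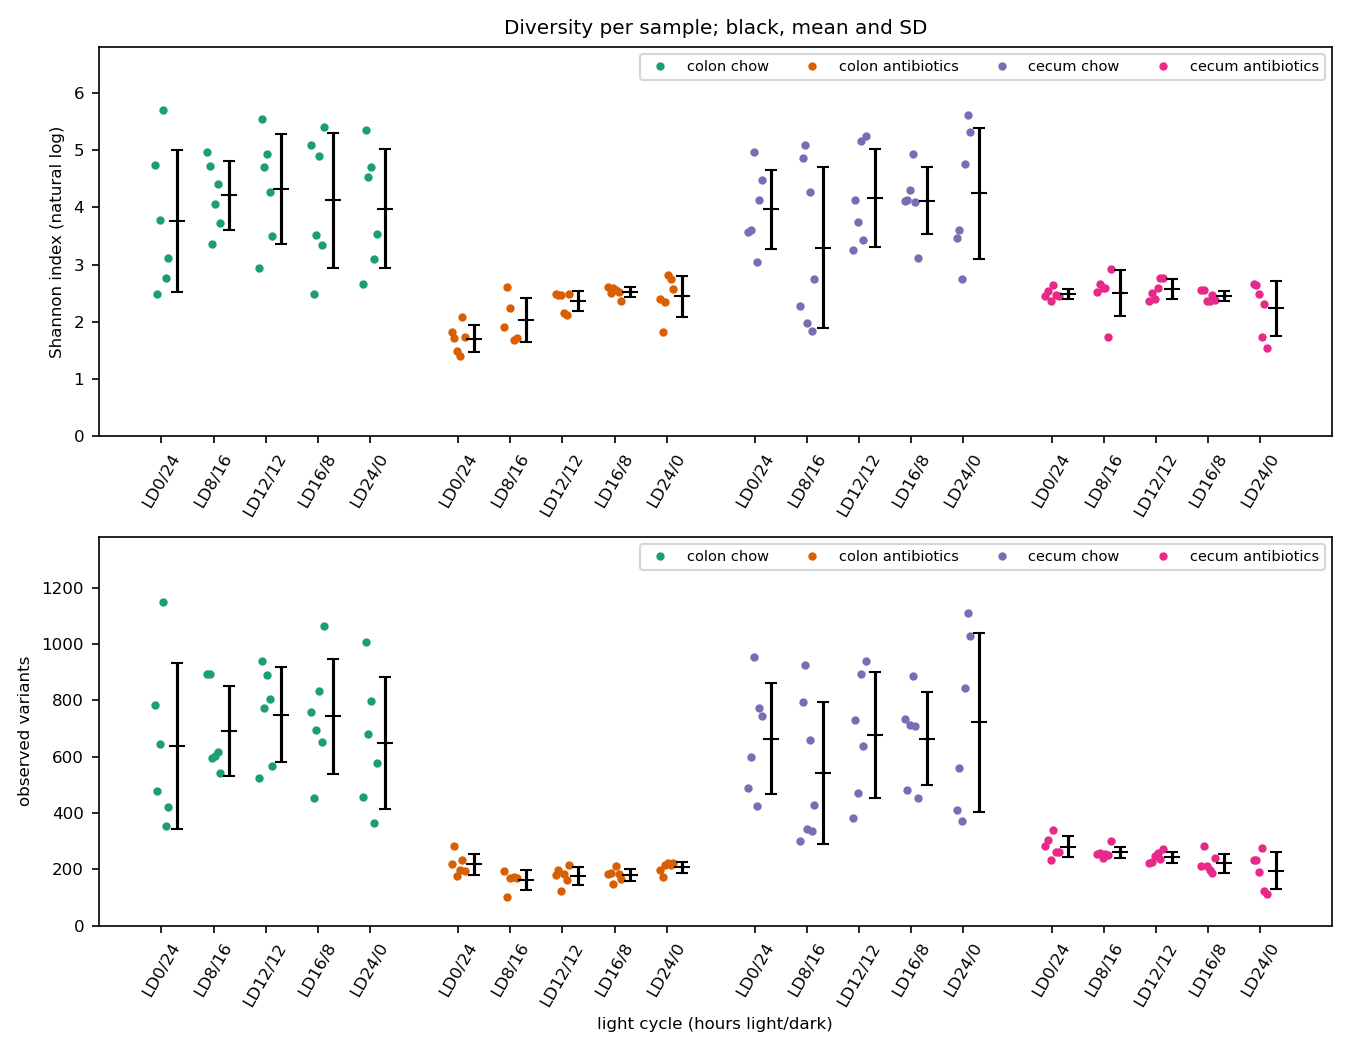
Shannon index and observed variants per sample by site, diet and light cycle (hours of light and dark); points are samples and black marks are means with SD. In the colon with antibiotics the Shannon index averages 1.70 in LD0/24 and 2.36 in LD12/12.

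The interaction test asked whether light cycles act differently on the diets. In the colon 27 of 118 genera passed, 8 of them background genera, led by Escherichia (edgeR adjusted p = 1.54e-09), which averaged 0.237% in LD24/0 with antibiotics. In the cecum 21 of 97 passed, led by Bacteroides and Lysinibacillus (adjusted p = 0.000117 for each). Of genera reaching 2% in a sample, 7 of 37 passed in the colon and 1 of 36 in the cecum. The interaction was not fitted with the set as a block, and the diets of a light cycle lie in different sets, so it is confounded with set.

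**Figure D5:**
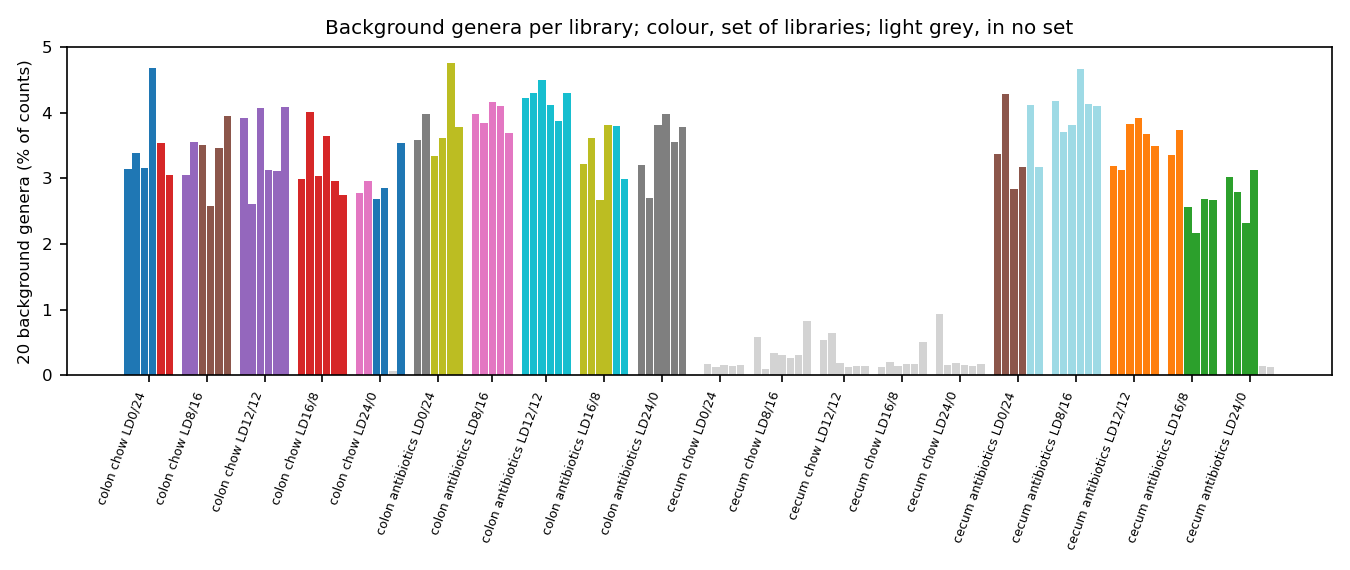
Share of counts (percent) of the 165 variants of the 20 background genera in each library, with colour giving the set of libraries and light grey libraries in none. Means are 3.21% in the colon on chow and 0.269% in the cecum on chow.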

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

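The sets of libraries and the tests that use the order of replicate numbers in sets, carry-over between libraries in colon chow, contrasts that share no set, centred log-ratios in the cecum on chow alone, the 2 contrasts that lost most calls with TMMwsp factors, the size of changes with the set as a block, and different sets at the sites were chosen only after the result was seen. The share of calls kept with the set as a block was chosen after the data were examined, with its bound set before that fit. The other tests were chosen before. A planned count of genera that differ between sets within light cycles was dropped, since the sets were made from the background genera among them.

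The first pattern is that the background genera lay at even levels in sets of about 8 libraries that crossed light cycles. Light cycle as their only source is argued against by the replicate numbers, which were not used to make the sets. In 7 of the 7 groups of 1 site, diet and light cycle divided between sets, the numbers of each set ran on unbroken among placed libraries (exact p = 1.12e-06). Replicate 5 of colon chow LD24/0, which lies in no set, was skipped. A candidate explanation is carry-over between libraries handled together. Klebsiella, Parabacteroides, Bacteroides, Enterococcus and Pantoea together took 1.61% to 3.70% of counts in the 29 placed colon chow libraries and 0.189% in the other, and no difference between sets within light cycles was detected (permutation p = 0.745). A p of 0.05 or more had been set as the value that excludes carry-over, but a missed threshold excludes nothing, so that bound was wrong and the explanation stays open.

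The second pattern is the genera called between light cycles. With the set as a block, 0% of the 57 calls against LD12/12 in the 6 separable contrasts were kept, which met the bound of under 25% set before that fit for sets of libraries as the cause, and 44 kept their sign. Of these calls, 19 and 25 are of LD0/24 and LD24/0 in colon antibiotics and 12 of LD24/0 in cecum antibiotics. No set holds these light cycles together with LD12/12, and they are linked to it only through LD16/8. Of LD16/8, only replicates 5 and 6 in the colon and 1 and 2 in the cecum share a set with LD12/12. A loss of calls was thus likely whatever the cause and cannot tell sets from light cycle. The median log2 fold change in the direction of the call was 5.13 with a median SE of 1.55, and 0.83 with 2.36 with the block, a ratio of 0.161, so the changes shrank and the error grew, while in 6 other contrasts light cycle and set cannot be told apart, as no chain of shared sets links the light cycle to LD12/12. A few genera taking most of the counts are argued against for the calls for any light cycle, since 67.1% of the 152 were also made with centred log-ratios, but this stays open in the cecum on chow, at 41.4% of 29, and for LD0/24 in colon antibiotics and LD24/0 in cecum chow, where 15.4% of 26 calls were kept with TMMwsp factors and 53.8% with centred log-ratios, the median log2 fold change being 5.83 (median SE 1.70) before and 5.64 (1.69) with TMMwsp. Sets are thus a candidate explanation for the 57 calls, while the 6 genera of the colon with antibiotics called for any light cycle in both fits leave a biological light effect open, although this test has no direction and Anaeroplasma, 1 of the 6, turned to -3.19 in LD0/24 with the block, and the summed shares of Enterobacterales and of enterococci and staphylococci did not pass with it (adjusted p = 0.0521 and 0.0999). Cage is not given and was not tested for any of these calls.

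The third pattern is that Klebsiella, Enterococcus and Pantoea together took 45.9% ± 19.1 (SD, n = 29) of counts in the colon and 18.4% ± 6.24 (SD, n = 30) in the cecum with antibiotics. Carry-over is argued against, as the difference was 19.3 times the highest share in any chow library, 1.42%. A few genera taking most of the counts are argued against only as the whole explanation: with Parabacteroides left out of the total, the shares were 69.9% ± 20.8 (SD) and 57.9% ± 17.6 (SD), and the difference went from 27.4 to 11.7 percentage points (permutation p = 0.0256). With 0 sets holding antibiotics samples of both sites, set and site cannot be told apart, so a difference between sites may be one between sets.

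Single samples lay far from the others of their group in 36 of 260 tests, against about 13 by chance. For the Shannon index this was cecum antibiotics LD8/16 replicate 5 at 1.74. For observed variants it was colon antibiotics LD8/16 replicate 2 at 100.4 and cecum antibiotics LD8/16 replicate 6 at 300.2. For total counts it was colon chow LD24/0 replicate 5 at 39157, which also had 0.0587% of background genera and 0.0153% of Enterobacterales. Other shares of background genera were 4.68% in colon chow LD0/24 replicate 4, 0.00444% in cecum chow LD0/24 replicate 1, 0.503% in cecum chow LD16/8 replicate 6 and 0.932% in cecum chow LD24/0 replicate 1. Lactic acid bacteria and bifidobacteria reached 5.69% in colon antibiotics LD12/12 replicate 1. Enterobacterales reached 10.4% in cecum chow LD8/16 replicate 2, 1.29% in cecum chow LD24/0 replicate 5 and 36.6% in cecum antibiotics LD8/16 replicate 4. Enterococci and staphylococci took 18.6% in colon antibiotics LD8/16 replicate 2, 22.6% in colon antibiotics LD12/12 replicate 3, 0.192% in cecum chow LD0/24 replicate 4, 0.0849% in cecum chow LD24/0 replicate 5, 4.41% in cecum antibiotics LD8/16 replicate 6 and 2.16% in cecum antibiotics LD12/12 replicate 5.

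Mucin degraders and mucus-layer genera took 0.805% in colon chow LD0/24 replicate 4, 7.07% in colon chow LD24/0 replicate 2, 3.77% in cecum chow LD0/24 replicate 6, 2.50% in cecum chow LD8/16 replicate 2, 0.0481% in cecum antibiotics LD8/16 replicate 6 and 0.029% in cecum antibiotics LD12/12 replicate 6. Sulfate reducers took 11.2% in colon chow LD24/0 replicate 2, 0.573% in colon antibiotics LD24/0 replicate 4, 45.9% in cecum chow LD24/0 replicate 3, 1.73% in cecum antibiotics LD0/24 replicate 4 and 1.04% in cecum antibiotics LD24/0 replicate 4. Erysipelotrichales took 6.12% in colon chow LD12/12 replicate 1, 0.00537% in colon antibiotics LD8/16 replicate 2 and 23.5% in cecum chow LD16/8 replicate 2. Reagent and environmental genera with plastids took 1.35% in cecum antibiotics LD0/24 replicate 2 and 1.17% in cecum antibiotics LD8/16 replicate 4.

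The test of whether light cycle effects differ between diets passed for 27 genera in the colon and 21 in the cecum by edgeR. It was not fitted with the set as a block, and the sets are confounded with it, as the diets of a light cycle lie in different sets and no cecum chow sample lies in one. In the colon the adjusted p was 1.54e-09 for Escherichia, 1.14e-07 for Lentilactobacillus, 2.99e-07 for Fusobacterium, 1.73e-06 for Actinomyces, 4.25e-06 for Rothia and 7.9e-06 for Levilactobacillus. In the cecum it was 0.000117 for Bacteroides and for Lysinibacillus, 0.00015 for Neisseria, 0.000545 for Haemophilus and for Rothia, and 0.000977 for Actinomyces.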

How the results depend on the processing

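The set of libraries as a block, genera reaching 2% in a sample, and the diets within 1 set were chosen only after the result was seen. The direction and the side of the threshold of the diversity results of diets held under every alternative run, and those of sites except as given here. The cause was not tested unless stated. Depth limits the rare genera, as those without 3 counts in 5 samples of a fit were not tested.

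With fewer genera tested (those reaching 2%), counts were 37 and 36 for antibiotics against chow in colon and cecum, 1, 9, 2 and 1 for any light cycle in colon chow, colon antibiotics, cecum chow and cecum antibiotics, and 8 and 7 for cecum against colon on chow and with antibiotics. They were 7 and 1 for the interaction in colon and cecum. Against LD12/12 they were 0, 1, 0 and 0 for LD0/24, LD8/16, LD16/8 and LD24/0 in colon chow, 4, 3, 0 and 1 in colon antibiotics, 0 for LD24/0 in cecum chow, and 0, 1 and 1 for LD0/24, LD8/16 and LD24/0 in cecum antibiotics. Within 1 set, 31 of 60 genera passed between diets in the colon, but its 5 antibiotics samples are all of LD8/16 and its 2 chow samples of LD24/0, so diet and light cycle are confounded there.

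With the set as a block, counts were 0, 6 and 0 for any light cycle in colon chow, colon antibiotics and cecum antibiotics, 0, 0 and 3 for LD0/24, LD16/8 and LD24/0 in colon antibiotics, and 0 for LD24/0 in cecum antibiotics. Observed variants did not pass between light cycles in colon antibiotics (F = 1.53, permutation p = 0.195) or cecum antibiotics (F = 0.511, permutation p = 0.604), nor did composition in cecum antibiotics (R2 = 0.117, permutation p = 0.282). Changes of named genera turned direction, none passing, to -0.23 for unclassified Chloroplast and -3.19 for Anaeroplasma (LD0/24, colon antibiotics), and to 0.11 and 0.79 for Pediococcus (LD24/0, colon and cecum antibiotics). LD8/16 in colon chow and LD16/8 in cecum antibiotics had 0 calls with this block, as without it. The other contrasts against LD12/12 could not be fitted with it.

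With no filter, counts were 95, 128 and 55 for any light cycle in colon chow, cecum chow and cecum antibiotics, 1 for LD8/16 in colon chow, 5 and 14 for LD0/24 and LD24/0 in colon antibiotics, 9, 8, 7 and 3 for LD0/24, LD8/16, LD16/8 and LD24/0 in cecum chow and 8 for LD0/24 in cecum antibiotics. With DESeq2 they were 11 for any light cycle in cecum chow, 10 and 1 for LD0/24 and LD8/16 in colon chow, 4 for LD16/8 in colon antibiotics, 5, 5, 1 and 4 for LD0/24, LD8/16, LD16/8 and LD24/0 in cecum chow, and 4 for LD0/24 in cecum antibiotics. With TMMwsp factors they were 10 for LD0/24 in colon chow, 4 for LD0/24 in colon antibiotics, 5 and 0 for LD0/24 and LD24/0 in cecum chow and 1 for LD0/24 in cecum antibiotics. With limma on centred log-ratios they were 16 for any light cycle in cecum chow, and 134 and 122 for cecum against colon on chow and with antibiotics. With the replicate number as a block they were 26 and 16 for any light cycle in colon antibiotics and cecum chow, 5, 6 and 0 for LD0/24, LD8/16 and LD16/8 in colon antibiotics, 2 for LD8/16 in cecum chow, 1 and 7 for LD0/24 and LD24/0 in cecum antibiotics, and 44 for cecum against colon on chow.

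On genera in place of variants, the Shannon index did not pass between light cycles in colon antibiotics (F = 2.19, permutation p = 0.102), and its difference between cecum and colon with antibiotics reversed to -0.276. At a depth of 500, observed variants did not pass between light cycles in cecum antibiotics (F = 2.42, permutation p = 0.0679). Composition differed between light cycles in colon chow with Jaccard (R2 = 0.175) and Aitchison distance (R2 = 0.284), and in cecum chow with Aitchison distance (R2 = 0.188). Neither of these distances was run with the set as a block. With 1 sample left out, counts for LD8/16 against LD12/12 in colon antibiotics ranged from 6 to 12, with 6 without LD8/16 replicates 2 or 5, and 7 without LD8/16 replicate 4 or LD12/12 replicates 2, 3 or 4. Of named genera, 5 of 6 for any light cycle in cecum chow (UCG-005, unclassified Christensenellaceae, unclassified Staphylococcaceae, Escherichia-Shigella and Lachnospiraceae UCG-001) and 3 of 8 in cecum antibiotics (Bifidobacterium, Ruminococcus gnavus group and Enterococcus) lost their call in at least 1 such fit, as did Bacteroides for LD8/16 in colon antibiotics. R2 for light cycle in cecum antibiotics ranged from 0.24 to 0.325, not passing without LD24/0 replicate 6 (permutation p = 0.075). Of named genera, 143 kept direction and call with TMMwsp factors and 12 did not pass, 150 and 2 with DESeq2, 140 and 15 with no filter, 128 and 27 with the replicate number as a block, 96 and 10 with limma on centred log-ratios, 43 and 4 among genera reaching 2%, and 2 and 39 with the set as a block, apart from the 4 given.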

Other observations

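Other splits of the samples were counted for every test across genera, in 100 splits each with the real one included; these tests were chosen before the result was seen. For antibiotics against chow, 1 split, the real one, gave as many genera, with 141 and at most 30 in the others in the colon and 191 and at most 70 in the cecum. For cecum against colon, 1 split gave as many, with 85 and at most 22 on chow and 68 and at most 26 with antibiotics. For any light cycle, 1 split gave as many, with 49 and at most 6 in colon chow, 46 and at most 2 in colon antibiotics, 29 and at most 16 in cecum chow and 28 and at most 5 in cecum antibiotics. For the interaction, 1 split gave as many, with 27 and at most 10 in the colon and 21 and at most 16 in the cecum. Chance is argued against for these results, within the 100 splits counted.

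Against LD12/12, chance is argued against in colon chow for LD0/24 (1 split, 4 genera, at most 2 otherwise) and LD24/0 (1 split, 40 and 1). It is also argued against in colon antibiotics for LD8/16 (1 split, 12 and 2) and LD24/0 (1 split, 25 and 0). For LD16/8 in colon chow (2 splits, 8 and 8) and LD0/24 in colon antibiotics (2 splits, 19 and 19), another split gave as many, so chance stays open. For LD16/8 in colon antibiotics, 4 splits gave as many as the 1 genus called, with 1 the highest other, and 0 genera were called with the replicate number or the set as a block. Chance is argued against for LD24/0 in cecum chow (1 split, 7 and 0) and in cecum antibiotics (1 split, 12 and 6). For LD0/24 (2 splits, 2 and 2) and LD8/16 (2 splits, 14 and 14) in cecum antibiotics, another split gave as many, so chance stays open. Where 0 genera were called, all 100 splits necessarily gave as many, so the count of splits cannot test chance there. The contrasts with 0 genera are LD8/16 in colon chow with at most 1 in the others, LD0/24, LD8/16 and LD16/8 in cecum chow with at most 2, 2 and 0, and LD16/8 in cecum antibiotics with at most 2. The shares of splits were not adjusted over the contrasts. These splits do not separate light cycle from set of libraries.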
